A study of Danio rerio with 48 samples.

How the data were processed

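The measurement was messenger RNA in the heads of zebrafish larvae. Per the labels' protocols, embryos were exposed from 0 dpf in single wells with a daily change of medium, and 15 heads were pooled per sample. RNA was selected by its polyA tail from 500 ng of total RNA. Libraries were amplified for 13 PCR cycles with 16 index primers, randomised into 3 sequencing pools of 16 libraries, and read for 75 cycles from a single end. The 48 libraries fell into 8 groups of 6 by concentration (0, 7.87, 14 and 25.1 µM PFHxS, all in 0.4% DMSO) and age (4 and 5 dpf), as the treatment, concentration and age labels give them. A letter from A to I in the sample titles was taken as the replicate name. Nothing in the labels says that pools came from separate clutches, so p-values measure the spread between pooled samples, which may be partly technical.

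Values of 2 kinds had been made by the authors. The deposited table of expected counts holds estimated reads per gene, not normalized, for 25445 genes; 77.5% of its values were whole within a tolerance of 1e-09, and the smallest total of a gene was 10. The other deposited table holds log2 values after quantile normalization for 19844 genes, whose smallest linear value was 1e-04. Per the submitters' processing notes, STAR 2.5.3a and Partek 8.0.19.0428 were used with the genome build GRCz11. The role of each tool, the annotation release and the handling of reads shared between genes or strands were not given in the sources used here. Members of gene families with near-identical copies, such as globins and crystallins, are therefore uncertain. Coordinates are those of the deposited table, on GRCz11. Of the gene symbols, 16215 were matched in the table of names; no reference genome was used here.

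Expected counts were rounded to whole numbers. Total counts per library ran from 16.6 to 39.2 M (1 M is 1000000 counts), with a median of 22.9 M, and scaling factors by the trimmed mean of M values (TMM) from 0.566 to 1.098 at 4 dpf and from 1.1 to 1.925 at 5 dpf. Genes were kept with edgeR's filterByExpr on the 8 groups, which left 20723. All 48 libraries were fitted in 1 model of 8 group means with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (glmQLFit and glmQLFTest), with edgeR's default prior count and no covariate. The biological coefficient of variation was 0.361. Each concentration was compared with DMSO of the same age, 5 dpf with 4 dpf in DMSO, and the 25.1 µM effect between ages as an interaction. Slopes against concentration were fitted on the 24 libraries of an age. P-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold, and the SE of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled counts per 1000000. Log2 CPM values, used for the principal components and the lists, had a prior count of 2.

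The design, the gene lists, the rule for named genes and a set of alternatives were chosen before the data were examined. Named genes have a descriptive symbol and an average log2 CPM of at least 1. Where none passed the threshold, the 3 genes with the smallest p were named; between ages the 10 largest rises, the 10 largest falls and up to 10 list members were. The PPAR and RXR receptor genes and their coactivators and corepressors, with angptl4, cpt1b, plin2, fabp10a, rho, cyp1a and fkbp5, were named whatever their values, 22 genes in all. The 44 lists covered metabolism, vision, neurotransmission, stress axes, cell types of the head and organs that a dissected head could carry. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one, and with fry. The mean log2 CPM of a list in each library was compared between groups with an exact permutation test, two-sided, over all 924 splits of 12 libraries, for which the smallest possible p is 0.00216.

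Alternatives fixed in advance were DESeq2 1.42.0 with its default filtering at 0.1, limma on the quantile values with a pseudocount of 1, size factors by relative log expression, a minimum of 1 CPM in 6 libraries or no filter on low counts, a minimum change of 1.5-fold, surrogate variables from sva 3.50.0 (at most 5), fits on fewer libraries, the letter as a block, other concentration scales, and each library left out in turn. Those chosen after seeing the data were a term for the column block, terms for the liver, exocrine pancreas and intestine scores, robust dispersion, DESeq2 filtering at 0.05 or on unfiltered genes, the exact test of list means, filtering on the 4 groups of an age, and 2 sets of left-out libraries. The sets were 3 libraries in which the 10 most counted genes held under 15% of counts, and 4 libraries at 5 dpf with an exocrine pancreas score under 0.

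The column block stands for a sequencing pool that the labels do not name. In the count table the last 16 columns carry each of 16 index numbers once, and the first 32 carry each on 2 libraries, so the last 16 were taken as 1 pool; this was inferred, and the first 32 could not be divided. Of the DMSO libraries 4 at 4 dpf and 1 at 5 dpf were in the last 16. At 7.87 µM there were 0 and 3, at 14 µM 2 and 2, and at 25.1 µM 2 and 2. All 1128 pairs of libraries were checked for duplicates by chi-square over genes. The test was run on simulated counts for 20723 genes, drawn independently with 1 dispersion per gene for all groups. Of 200 changed genes, 50 were at each of 4 fold sizes from 1.5 to 4. At 4-fold the test recovered 96% at 4 dpf and 100% at 5 dpf, with 5 and 7 false calls. The recovery rates hold for 200 genes changed together, and a case with only a few changed genes was not simulated.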

Results

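The heads of zebrafish (Danio rerio) larvae exposed to perfluorohexanesulfonate (PFHxS), given as its potassium salt, were sequenced as polyA RNA. PFHxS is a fluorinated surfactant of the PFAS family. The title of the series asks which key events of PFAS exposure bear on the larval light:dark assay, a test in which swimming is recorded while the light is switched on and off. Exposure began at 0 days post fertilisation (dpf), with the medium renewed daily, and heads were taken at 4 or 5 dpf. At each age there were 4 groups: the vehicle (0.4% DMSO) and PFHxS at 7.87, 14 and 25.1 µM. Each of the 8 groups held 6 libraries, and each library came from a pool of 15 heads severed in front of the swim bladder. Total counts ran from 16.6 to 39.2 M per library (1 M is 1000000 counts), with a median of 22.9 M.

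Age was the main axis of the 48 libraries. The first principal component of log2 counts per 1000000 (CPM) held 45.2% of the variance. Scores ran from -142.1 to -0.1 at 4 dpf and from 28.1 to 106.7 at 5 dpf. The libraries of 7.87 µM varied most among themselves. The median SD of log2 CPM over 14335 genes was 0.586 at 4 dpf and 0.409 at 5 dpf, against 0.338 and 0.264 in DMSO. At 25.1 µM it was 0.347 and 0.301. The most counted genes were the long noncoding RNA gene CT027638.1 (chromosome 20, 55169000 to 55169890, GRCz11), with a mean of 5.82% of counts, and zgc:158463 (chromosome 5, 824709 to 825921), with 5.79%. They were followed by the cartilage collagen gene col2a1a with 2.29% and the elongation factor gene eef2b with 2.17%. Among the 1128 pairs of libraries none agreed within sampling noise, since the smallest chi-square per gene was 14.1.

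**Figure D1:**
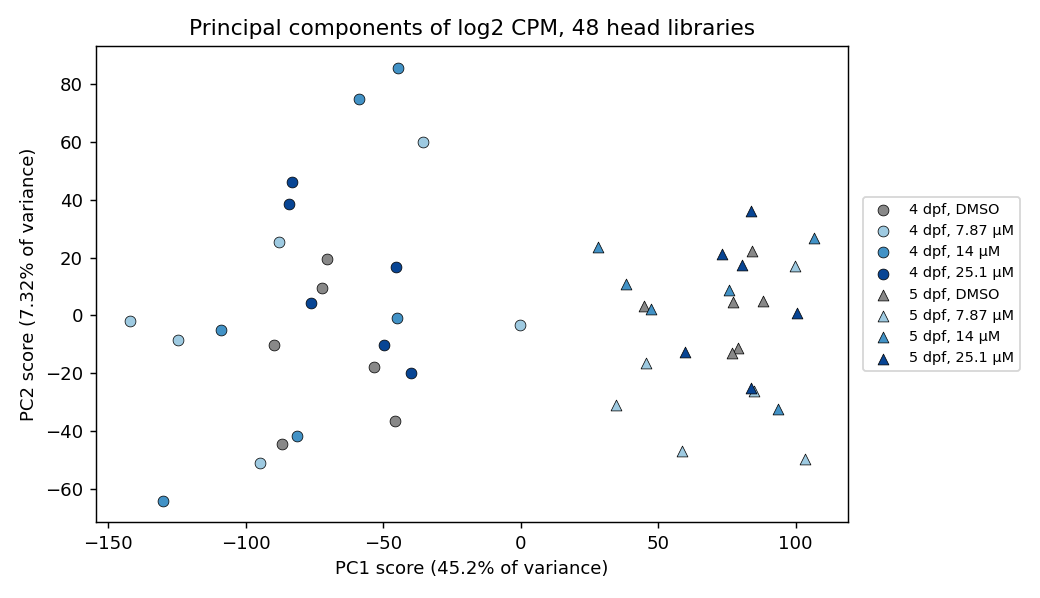
Scores of the 48 libraries on principal components 1 (horizontal axis, 45.2% of variance) and 2 (vertical axis, 7.32%) of log2 CPM; each point is 1 library, circles are 4 dpf, triangles are 5 dpf, and darker blue is a higher concentration of PFHxS. All 4 dpf libraries lie at or below -0.1 on component 1 and all 5 dpf libraries lie at or above 28.1, while the concentrations overlap.

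The first question was which genes differed between 25.1 µM and DMSO in the 4 dpf head. Genes of the digestive organs stood higher in the exposed libraries. Of 69 liver genes 65 had a positive log2 fold change, with a median of 1.14, and all 20 exocrine pancreas genes and 38 of 44 intestine genes were positive, with medians of 1.43 and 0.82. The mean log2 CPM over the liver list was 3.17 ± 0.549 (SD, n = 6) at 25.1 µM and 2.07 ± 0.832 in DMSO. The fabp10a gene, which encodes the liver fatty acid binding protein, had 27.5 ± 27.5 CPM against 8.47 ± 11.4 (SD, n = 6). This was a log2 fold change of 1.72 ± 0.77 (SE). The ratio of the mean CPM was 3.25, and it was 1.99 without library E of 25.1 µM and 7.12 without library E of DMSO. Among 54 genes of the pregnane X receptor and xenobiotic metabolism list 45 were positive, with a median of 0.69. The PPAR target list, genes activated by the fatty acid receptors, had 27 of 34 positive and a median of 0.19. At 14 µM and 4 dpf the liver, pregnane X receptor and PPAR target means were all highest in library D (4.68, 1.3 and 2.71). They were lowest in library H (-0.42, -0.94 and 1.77). Within 25.1 µM library H had liver and pregnane X receptor means of 2.68 and 1.03, and B 3.59 and 0.58. Part of these rises may go with liver content, which was not tested for these lists.

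Camera with a preset correlation called 20 of the 44 lists, 17 as higher and 3 as lower, and none held with an estimated correlation. The liver list had an adjusted p of 3.98e-25, and adjusted p = 0.423 with an estimated correlation. For the exocrine pancreas the adjusted p was 0.000448, and adjusted p = 0.711 with an estimated correlation. For the intestine it was 1.1e-06, and adjusted p = 0.447 with an estimated correlation. The PPAR target list had 0.00473, and adjusted p = 0.447 with an estimated correlation. The pregnane X receptor list had 1.29e-07, and adjusted p = 0.447 with an estimated correlation. The exact two-sided permutation test of the liver list mean gave a difference of 1.1 and p = 0.0281, or 0.238 after adjustment over the 44 lists. In all, 7 lists had an exact p under 0.05 and none passed after adjustment. The smallest belonged to kidney and ionocyte (difference 0.252, exact p 0.00866) and to myelin and oligodendrocyte (-0.177, exact p 0.0152), both with an adjusted p of 0.238. By sequencing pool, as far as the order of columns shows it, the difference was 1.1 in the first 32 columns of the table (4 exposed, 2 DMSO libraries) and 1.06 in the last 16 (2 exposed, 4 DMSO).

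Lists tied to vision, signalling in the brain and daily rhythm had medians nearer to 0. The circadian clock and light-regulated list had 8 of 44 members positive and a median of -0.17, with an adjusted p of 0.000364, and adjusted p = 0.447 with an estimated correlation. Of 38 glutamatergic genes 5 were positive (median -0.18; adjusted p 0.0103, and adjusted p = 0.739 with an estimated correlation). Of 39 synaptic vesicle genes 6 were (median -0.14; adjusted p 0.0261, and adjusted p = 0.739 with an estimated correlation). The phototransduction list, which holds the opsins and their signalling chain, had 30 of 58 positive, a median of 0.00 and an adjusted p of 0.863. Skeletal muscle had 56 of 61 positive and a median of 0.33 (adjusted p 1.59e-16, and adjusted p = 0.423 with an estimated correlation). The hypothalamic-pituitary-interrenal list, the stress axis of fish, had a median of -0.13 and a mean of 0.22, and camera put it on the higher side with an adjusted p of 0.831. The lens list (-0.03 and 0.01) and the thyroid axis (-0.02 and 0.08) also had a median and a mean of different sign, and phototransduction had a positive mean with camera on the lower side.

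No gene passed edgeR's quasi-likelihood test at 25.1 µM and 4 dpf. An adjusted p under 0.05 was found for 0 of 20723 genes, and 540 (2.61%) had an unadjusted p under 0.05 (859 without library H of 25.1 µM). DESeq2 and limma on the authors' quantile values also called 0. Among genes with a descriptive symbol and an average log2 CPM of at least 1, the smallest p values belonged to nr5a5, a gene of the NR5A nuclear receptor family (chromosome 3, 53457192 to 53465250; log2 fold change 2.26 ± 0.60, SE), cables2b (chromosome 23, 9088191 to 9137649; -1 ± 0.28) and rabep2 (chromosome 3, 26157073 to 26171669; -0.68 ± 0.19). Each had an adjusted p of 1. Expression of nr5a5 was 3.14 ± 1.41 CPM at 25.1 µM and 0.66 ± 0.46 in DMSO, with 5 of 6 exposed libraries above every DMSO library. Of the 22 genes named whatever their values, log2 fold changes ran from -0.64 (pparab) to 1.72 (fabp10a), with adjusted p of 1 throughout. Of these, 2 had an unadjusted p under 0.05, fabp10a (0.0303) and cyp1a, the marker of the aryl hydrocarbon receptor (1.21 ± 0.58, 0.0419). Adjusted over the list alone, 1 member was called over all 44 lists, in the retinoic acid signalling list of 22 genes (median 0.04; adjusted p 0.0498, and adjusted p = 0.447 with an estimated correlation). Fitting the 12 libraries of these groups alone called 1 gene, ugt2a4.

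**Figure D2:**
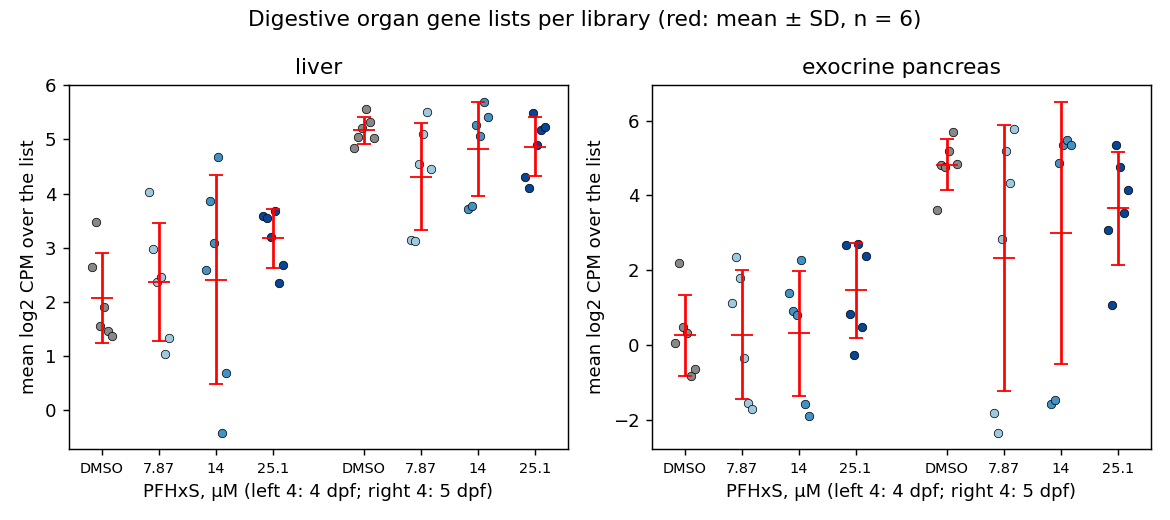
Mean log2 CPM over the liver list (left panel) and the exocrine pancreas list (right panel) in each library, against PFHxS concentration in µM, with 4 dpf in the left 4 columns of a panel and 5 dpf in the right 4; points are libraries and red bars are the mean ± SD of 6. At 4 dpf the liver mean was 3.17 at 25.1 µM and 2.07 in DMSO, and in DMSO both lists stood higher at 5 dpf.

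At 14 and 7.87 µM and 4 dpf the liver list had medians of 1.17 and 0.56, and camera adjusted p values of 0.00025 and 0.0419. With an estimated correlation the adjusted p was 0.902 and 0.875. The list means per library differed less from DMSO, by 0.345 (exact p 0.695) and 0.302 (exact p 0.602). At 14 µM they ran from -0.42 in library H to 4.68 in D, and without D the difference was -0.107. At 7.87 µM it was -0.029 without library A. Ribosomal protein genes had medians of 0.33 and 0.49 and genes of oxidative phosphorylation 0.29 and 0.42. At 7.87 µM the camera adjusted p values were 2.97e-09 and 3.61e-11, and adjusted p = 0.805 with an estimated correlation for both. Library I of 7.87 µM stood highest, with list means of 8.11 (others 6.97 to 7.42) and 6.14 (others 4.8 to 5.76). Genes of GABAergic and glycinergic transmission, the inhibitory synapses, had medians of -0.17 (adjusted p 0.0185, and adjusted p = 0.902 with an estimated correlation) and -0.37 (4.02e-05, and adjusted p = 0.805 with an estimated correlation). At 7.87 µM the phototransduction list was placed lower by camera (adjusted p 0.0419, and adjusted p = 0.851 with an estimated correlation), with a median of -0.09 and a mean of 0.015. Camera called 16 and 15 of the 44 lists, none of them with an estimated correlation. Among genes with a descriptive symbol and an average log2 CPM of at least 1, the 3 with the smallest p at 14 µM were itgb8, an integrin gene (chromosome 19, 2275019 to 2307723; -1.32 ± 0.29, SE; adjusted p 0.4), gadd45ga, a gene of the growth arrest and DNA damage family (1.52 ± 0.44; adjusted p 0.971), and stk38b (-1.11 ± 0.33; adjusted p 0.971). For gadd45ga the mean CPM was 2.87 times that of DMSO, and 1.58 times without library B of 14 µM. Under the same limits they were at 7.87 µM mrpl37, a mitochondrial ribosomal protein gene (chromosome 2, 10914023 to 10931771; 0.75 ± 0.17), tprg1 (chromosome 6, 28752943 to 28790320; 1.22 ± 0.27) and coq9, a gene of coenzyme Q synthesis (chromosome 25, 14381405 to 14398282; 1.2 ± 0.28), with an adjusted p of 0.209 for each.

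In edgeR's test 0 genes passed at either concentration, with 1046 (14 µM, 5.05%) and 2482 (7.87 µM, 12%) at an unadjusted p under 0.05. The 1046 became 696 without library B and 1605 without library I of 14 µM, and the 2482 became 1651 without library H of 7.87 µM. DESeq2 called 1 gene at 14 µM, the RNA-binding protein gene rbms1b (chromosome 9, 51655636 to 51755759; edgeR log2 fold change -2.10 ± 0.44), as did limma on the quantile values. Without library I of 14 µM edgeR called it too, and the ratio of its mean CPM moved from 0.212 to 0.129. At 7.87 µM DESeq2 called 10 genes, 8 higher and 2 lower, among them mrpl37, tprg1 and coq9, and limma called 0. Without library F of the DMSO group edgeR called 128 genes at 7.87 µM, 117 higher and 11 lower, and without library A of 7.87 µM it called 2, npl and spout1. All 6 libraries of 7.87 µM stood in the first 32 columns of the table against 2 of 6 DMSO libraries, so no value within the last 16 could be had. With the column block as a term 1034 genes had an unadjusted p under 0.05. Adjusted over the list alone, 39 members were called at 7.87 µM over the 44 lists and 1 at 14 µM. The genes named here beyond the 3 smallest p under those limits were chosen after their values were seen.

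At 5 dpf the comparison of 25.1 µM with DMSO put si:dkey-61n16.5 and six7 first. Expression of six7, a homeobox transcription factor gene that acts in cone photoreceptors (chromosome 7, 7401692 to 7420302), was 61.8 ± 17.4 CPM (SD, n = 6) at 25.1 µM and 37.4 ± 7.63 in DMSO, a log2 fold change of 0.72 ± 0.16 (SE). For six7, 5 of 6 exposed libraries lay above every DMSO library. The gene si:dkey-61n16.5, protein-coding per the deposited table, lies on chromosome 3, 13911950 to 13921174, per GRCz11. It had 80.8 ± 23.1 CPM against 32 ± 5.83, a log2 fold change of 1.34 ± 0.27, with 6 of 6 exposed libraries above every DMSO library. The cytochrome P450 gene cyp2k18 (chromosome 3, 12710350 to 12715433; 1.99 ± 0.62) and the ammonium transporter gene rhcgl1 (chromosome 6, 36381709 to 36391688; 1.57 ± 0.53) came next among genes with a descriptive symbol and an average log2 CPM of at least 1. None passed edgeR's test. The adjusted p was 0.264 for si:dkey-61n16.5, 0.617 for six7 and 1 for cyp2k18 and rhcgl1. Within the first 32 columns the mean difference in log2 CPM was 0.51 for six7 and 1.29 for si:dkey-61n16.5 (4 exposed, 5 DMSO libraries). In the last 16 it was 1.07 and 1.1 (2 exposed, 1 DMSO).

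**Figure D3:**
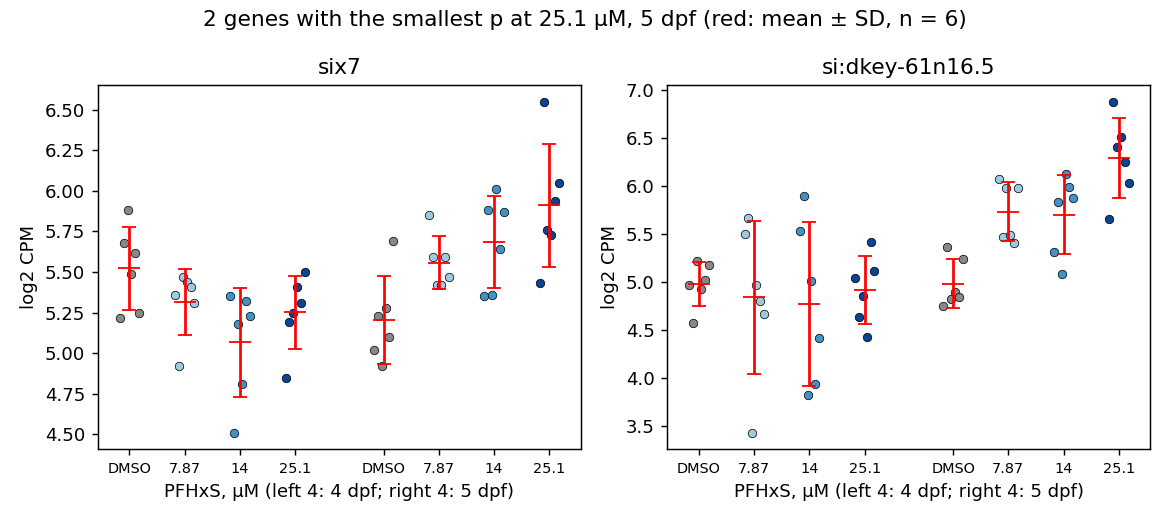
Log2 CPM of six7 (left panel) and si:dkey-61n16.5 (right panel) in each library, against PFHxS concentration in µM, with 4 dpf in the left 4 columns of a panel and 5 dpf in the right 4; points are libraries and red bars are the mean ± SD of 6. At 5 dpf 6 of 6 libraries of 25.1 µM lay above every DMSO library for si:dkey-61n16.5 and 5 of 6 for six7.

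The digestive lists lay on the lower side at this age. The exocrine pancreas list had 1 of 20 members positive and a median of -0.87 (adjusted p 2.35e-05, and adjusted p = 0.835 with an estimated correlation), and the liver list 16 of 69 and -0.21 (0.0011, and adjusted p = 0.835 with an estimated correlation). The intestine list had 8 of 44 and -0.16 (0.00476, and adjusted p = 0.835 with an estimated correlation). The mean difference of the pancreas list was -1.16 over all libraries and -0.647 without library D of 25.1 µM. For the liver list it was -0.303, -0.15 without D and -0.192 without C of 25.1 µM, and for the intestine list -0.34 and -0.186 without C. By column block the pancreas difference was -0.642 in the first 32 columns (4 exposed, 5 DMSO libraries) and -2.21 in the last 16 (2 exposed, D among them, and 1 DMSO), and that of the liver list -0.227 and -0.377. The DMSO group of 5 dpf held no library of letter A or D. For letter D the pancreas mean was 1.07 at 25.1 µM, -1.46 at 14 µM and -2.35 at 7.87 µM. Letter and exposure cannot be told apart for these libraries. Letter C was low at 7.87 µM (-1.82) but not at 25.1 µM (3.07) or in DMSO (3.62). Glutamatergic genes again had 5 of 38 positive, with a median of -0.16 (0.000174, and adjusted p = 0.835 with an estimated correlation). Genes of cartilage and bone had 42 of 49 positive and a median of 0.19 (8.73e-05, and adjusted p = 0.835 with an estimated correlation). Immediate early genes, which neurons switch on when they are active, had 27 of 32 and 0.19 (0.0104, and adjusted p = 0.835 with an estimated correlation). Their mean in library I of 25.1 µM was 3.48 (others 3.95 to 4.37), below every DMSO library (3.65 to 4.25). Glucocorticoid target genes had 22 of 30 positive and a median of 0.15 (0.0124, and adjusted p = 0.835 with an estimated correlation). Among them fkbp5 had 151 ± 19.1 CPM against 97.6 ± 27.3, a log2 fold change of 0.63 ± 0.36 and an unadjusted p of 0.0836. The phototransduction list had 38 of 58 positive and a median of 0.09 (adjusted p 0.0805). PPAR targets had 20 of 34 positive and a median of 0.07 (adjusted p 0.144), with log2 fold changes of 0.48 ± 0.26 for cpt1b, a carnitine palmitoyltransferase of fatty acid oxidation, and 0.35 ± 0.32 for angptl4, an inhibitor of lipoprotein lipase. Median and mean differed in sign for 7 lists that camera did not call, those of fatty acid oxidation, cholesterol synthesis, monoaminergic transmission, Nrf2 targets, myelin, neutrophils and macrophages, and astrocytes.

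In edgeR's test 0 of 20723 genes passed at 25.1 µM and 5 dpf, and 139 (0.671%) had an unadjusted p under 0.05. With no effect a share of 0.05 would be reached on average, so the fit of all 48 libraries may be conservative here. Fitted on its 12 libraries alone the comparison gave 756. The 139 became 311 without library G of 25.1 µM and 273 without library C of DMSO. Limma on the quantile values called 0 and DESeq2 1, si:dkey-61n16.5. Fits of the 24 libraries of this age alone called 1 gene, and those of the 12 libraries of these groups alone 2, cyp2k18 and si:dkey-61n16.5. Adding surrogate variables called 3, these and six7. Camera called 12 of the 44 lists, 6 as higher and 6 as lower, and 0 with an estimated correlation. The exact permutation test of list means gave 2 lists at p under 0.05 and a smallest adjusted p of 0.887. Adjusted over the list alone, 0 members were called. In simulated counts with the means, depths and dispersions of these libraries, the same test recovered 12% of 50 genes changed 1.5-fold, 62% at 2-fold and 96% at 3-fold at 5 dpf. At 4 dpf it recovered 10%, 54% and 86%. The simulated counts were drawn independently for each gene, with 1 dispersion for all groups. They lack the unequal spread of the groups and any structure shared among libraries, so these rates may not carry over to the real data. All changed genes were also simulated together, and the test made 142 calls at 5 dpf and 128 at 4 dpf, against 0 in the real comparisons. The adjustment lets larger p-values pass when many genes are called. The rates would therefore be lower if only a few genes had changed, a case that was not simulated. In the real data si:dkey-61n16.5 had an edgeR p of 1.27e-05 at 5 dpf and did not pass.

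At 14 µM and 5 dpf the smallest p values among genes with a descriptive symbol and an average log2 CPM of at least 1 belonged to lim2.1, a lens membrane protein gene (0.74 ± 0.25, SE), to six7 (0.48 ± 0.16) and to ppih, a cyclophilin of the spliceosome (1.29 ± 0.44), each with an adjusted p of 1. At 7.87 µM, under the same limits, they belonged to fam32a (1.79 ± 0.42), to the translation initiation factor gene EIF1B (1.22 ± 0.29) and to the ubiquitin-conjugating enzyme gene ube2d1b (1.31 ± 0.35), each with an adjusted p of 0.986. For fam32a the ratio of the mean CPM was 3.43, and 2.22 without library I of 7.87 µM. The lens list had a median of 0.30 at 14 µM (adjusted p 4.05e-14, and adjusted p = 0.364 with an estimated correlation). The list of the retinal pigment epithelium and visual cycle, the recycling of the light-sensitive pigment, had 0.33 (2.87e-05, and adjusted p = 0.364 with an estimated correlation). At 7.87 µM the exocrine pancreas list had a median of -0.78 and the liver list -0.53, both with an adjusted p of 2.64e-10, and adjusted p = 0.914 with an estimated correlation. There 2 of 6 libraries, C and D, stood apart, with pancreas means of -1.82 and -2.35 (others 2.83 to 5.79) and liver means of 3.14 and 3.13 (others 4.45 to 5.5). The list means differed from DMSO by -2.49 (exact p 0.152; -1.56 without D) and -0.856 (exact p 0.0649). In edgeR's test 0 genes passed at either concentration, with 151 (14 µM, 0.729%) and 972 (7.87 µM, 4.69%) at an unadjusted p under 0.05. The 151 became 292 without library G of 14 µM and 229 without library C of DMSO. The 972 became 566 without library I of 7.87 µM and 587 without library I of DMSO. DESeq2 and limma also called 0 at both. At 7.87 µM the 972 became 185 without the 3 libraries whose 10 most counted genes held under 15% of counts. With surrogate variables 2 genes passed at 14 µM, cyp2k18 and bik, the latter a gene of the BCL2 family (edgeR 1.4 ± 0.34). At 14 µM camera placed the pregnane X receptor list lower (adjusted p 0.0356, and adjusted p = 0.821 with an estimated correlation) although its median was 0.02. In libraries A and D of 14 µM its mean was 1.53 and 1.51 (others 2.68 to 3.55), and these 2 were also low in exocrine pancreas (-1.58 and -1.46, others 4.88 to 5.48) and intestine (0.78 and 0.89, others 3.21 to 3.87). Camera called 19 lists at 14 µM and 12 at 7.87 µM, none of them with an estimated correlation, and adjusted over the list alone 0 members passed at either.

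A slope against concentration was tested at each age. At 5 dpf 1 gene passed, si:dkey-61n16.5, with a slope of 0.0482 ± 0.0082 log2 units per µM (SE) and an adjusted p of 0.0479 in edgeR; 428 genes had an unadjusted p under 0.05. Its expression was 32 ± 5.83 CPM in DMSO, 54.1 ± 11.4 at 7.87 µM, 53.7 ± 14 at 14 µM and 80.8 ± 23.1 at 25.1 µM (SD, n = 6). This gene, outside the rule for named genes, was chosen after its values were seen. With concentrations replaced by their ranks 0 genes passed, and with the letter as a block 0 passed too. Among genes with a descriptive symbol and an average log2 CPM of at least 1, the smallest p values belonged to six7 (0.0275 ± 0.0063 per µM), cyp2k18 (0.0885 ± 0.0213) and rhcgl1 (0.06 ± 0.0152), each with an adjusted p of 1. Expression of six7 stood at 37.4, 47.2, 52.2 and 61.8 CPM from DMSO to 25.1 µM. At 4 dpf 0 genes passed and 231 had an unadjusted p under 0.05; DESeq2's slope test also called 0. Under the same limits the smallest p values there belonged to dab2, an endocytic adaptor gene (0.0324 ± 0.0102), and to the pancreatic enzyme genes cel.2 (0.1135 ± 0.0369) and cpa5 (0.0878 ± 0.0293), with an adjusted p of 1.

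Whether the effect of 25.1 µM differed between ages was tested as an interaction. The difference was 1.00 ± 0.23 (SE) for six7, which had a log2 fold change of -0.28 ± 0.16 at 4 dpf, and 1.08 ± 0.35 for plag1, a zinc finger transcription factor gene; for nr5a5 it was -2.42 ± 0.78. None passed in edgeR. The adjusted p was 1 for each, 0 genes passed, 381 had an unadjusted p under 0.05, and DESeq2 and limma also called 0. The difference of the liver list means between ages had an exact permutation p of 0.0112 and an adjusted p of 0.414 over 44 lists. Camera called 13 lists, 2 as higher and 11 as lower at 5 dpf, and 0 with an estimated correlation, where the smallest adjusted p was 0.808. Across 14335 genes, which are not independent replicates, the 25.1 µM effects at the 2 ages, which share no library, had a correlation of -0.103 and the same sign in 51.8%.

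In DMSO alone, transcripts of digestion stood higher in the severed heads at 5 dpf than at 4 dpf. Age was confounded with any difference in collection or dissection between the ages, which cannot be told from development here. The intestinal peptide transporter gene slc15a1a rose from 0.244 ± 0.118 to 18.2 ± 6.51 CPM (SD, n = 6), a log2 fold change of 6.16 ± 0.97 (SE). The intestinal alkaline phosphatase gene alpi.2 rose by 6.09 ± 1.02, the astacin protease gene c6ast4 by 6.01 ± 1.26 and the pancreatic elastase gene ela2l by 5.88 ± 1.22. The other genes with the largest rises were tmprss15 (enteropeptidase), slc28a1, chia.1 (a chitinase), cyp3c3, cel.2 and cyp2ad2, with log2 fold changes of 5.59 to 5.75. With surrogate variables in the fit, 4 of these had negative log2 fold changes and did not pass: c6ast4 (-0.87), ela2l (-0.44), chia.1 (-0.053) and cel.2 (-1.34). Of 69 liver genes 60 rose and 1 fell, of 20 exocrine pancreas genes 17 rose and none fell. Of 44 intestine genes 32 rose and 3 fell, and of 54 genes of the pregnane X receptor and xenobiotic list 46 rose and 1 fell. Camera gave these lists adjusted p values of 1.04e-16, 4.33e-05, 7.21e-08 and 1.82e-15. With an estimated correlation the adjusted p was 0.349, 0.503, 0.349 and 0.301. Adjusted over the list alone, 62, 17, 36 and 47 members were called.

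Lens and embryonic blood genes were among those that fell. The secretory calcium-binding phosphoprotein gene scpp9 fell by 4.19 ± 0.56 on the log2 scale, the galectin gene lgals1l1 by 3.77 ± 0.57, fabp11b by 3.70 ± 0.73 and txnl4a by 3.18 ± 0.40. The embryonic globin genes hbbe1.3 (-2.96 ± 0.34) and hbbe1.2 (-2.84 ± 0.37) and the gamma crystallin genes crygm2d7 (-2.84 ± 0.45) and crygm2d21 (-2.81 ± 0.42) belong to families of near-identical copies. Their reads may be split among copies, so their values are uncertain. The remaining largest falls were lypc and sec11a. In the lens list 36 of 58 genes fell and 1 rose, and 38 were called when adjusted over the list alone. Among ribosomal protein genes 64 of 94 fell and 2 rose, and in nuclear-encoded oxidative phosphorylation 56 of 78 fell and 5 rose. Of these, 69 and 62 were called when adjusted over the list alone. These 3 lists had camera adjusted p values of 2.31e-11, 1.13e-12 and 3.22e-14. With an estimated correlation the adjusted p was 0.301, 0.349 and 0.349.

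List members with the smallest p included tat, a tyrosine aminotransferase that glucocorticoids induce (4.79 ± 0.47, chromosome 18, 13162728 to 13179511), dio3b, a thyroid hormone deiodinase (3.38 ± 0.36), spp1, the bone matrix gene osteopontin (2.90 ± 0.32), and rhcgb, an ammonium transporter of ionocytes (2.47 ± 0.28). Among those that fell were cps1 (-1.95 ± 0.21), the neuronal gene stmn2b (-1.89 ± 0.22), the cryptochrome gene cry4 (-1.80 ± 0.22) and crx, a photoreceptor transcription factor gene (-1.61 ± 0.19). Their edgeR adjusted p values ran from 1.33e-09 for tat to 3.32e-08 for cry4. Glucocorticoid targets (20 of 30 rose, 2 fell) and the fasting and gluconeogenesis list (14 of 18 rose, none fell) held with an estimated correlation, each with an adjusted p of 0.0447. Adjusted over the list alone 22 and 14 members passed. As drawn up, the 2 lists share pck1, pdk2b and foxo3b, so they are not independent results. The liver list rose as well, with a median of 3.41 under TMM, and its part in these rises was not tested. PPAR targets had 20 of 34 higher and 5 lower, with an adjusted p of 0.000693, and adjusted p = 0.349 with an estimated correlation. Of these, 26 passed when adjusted over the list alone. In the phototransduction list 8 of 58 rose and 23 fell (adjusted p 0.0332, and adjusted p = 0.639 with an estimated correlation), with 32 called when adjusted over the list alone; its median difference was -0.07 under TMM, 0.62 under total-count scaling and 0.12 under quantile scaling.

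In total 8682 genes passed edgeR's test between the ages, 4488 higher and 4194 lower at 5 dpf, and 5052 of them changed at least 2-fold. Camera called 24 lists, 2 with an estimated correlation, and fry 29. On the authors' quantile values limma called 3044 higher and 4098 lower. The all-gene median of the log2 difference was 0.22 under TMM, 0.87 under total-count scaling and 0 under quantile scaling. The ribosomal median was -1.03, -0.33 and -0.51 under these, and the cartilage and bone (-0.48), erythrocyte (-0.50) and cell proliferation (-0.43) medians turned to 0.22, 0.19 and 0.25 under total-count scaling. With surrogate variables the count was 1152, and with liver, exocrine pancreas and intestine scores as terms it was 3074, 990 higher and 2084 lower.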

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

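The tests of shared letters and of the phototransduction list were chosen only after the result was seen, as were the column block and the digestive scores as model terms and the liver fits on 12 libraries; the splits of the samples were planned. Over 27 quantities in 8 groups, 216 group values were examined for a sample far from the others of its group, and 9 were found, where chance alone gives about 10.8. Library F of 25.1 µM at 4 dpf had a total of 39.2 M counts, the others of its group 17.1 to 25.1. Its phototransduction mean was 6.16 log2 CPM (others 5.41 to 5.65) and its cyp1a level -0.43 (others 1.79 to 2.47). Library H of 7.87 µM at 4 dpf held 14.5% of its counts in the 10 most counted genes, the others 23.5% to 26.9%. At 4 dpf the intestine mean of DMSO library E was 1.66 (others 0.09 to 0.57), and tprg1 in DMSO library H was 0.19 (others 0.91 to 1.3). In 7.87 µM libraries six7 was 4.92 in B (others 5.31 to 5.47) and cyp1a -3.57 in I (others 0.73 to 2.3) at 4 dpf, and angptl4 was 4.17 in I at 5 dpf (others 5.70 to 6.59).

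Liver genes stood 1.1 ± 0.41 (SE) log2 units higher at 25.1 µM than in DMSO at 4 dpf over the 12 compared libraries, and 1.1 ± 0.7 with the spread of all 24 of that age. A difference in which letters the groups held is argued against: over the 4 letters in both groups the mean difference was 0.79 ± 0.22, higher in 4 of 4. The first 32 columns could not be divided, so a pool difference inside them was not tested. A difference between the last 16 columns and the first 32 as the whole cause is argued against over the 12 compared libraries. With the column block as a term the liver difference was 1.08 ± 0.45 over the 12 and 0.87 ± 0.72 over the 24. Within the blocks it was 1.1 and 1.06. With the exocrine pancreas and intestine scores as terms it was 0.57 ± 0.27 over the 12 and 0.19 ± 0.38 over the 24, so a varying amount of digestive tissue in the severed heads may give part or all of it and remains open. A response of those organs together would give it as well, and remains open. Chance remains open too, as the exact permutation test of the liver list mean had an adjusted p of 0.238. Outside the digestive organs, list means differed by 0.447 for skeletal muscle and 0.387 for heart, but by -0.177 for myelin and oligodendrocyte. Whether the heads differed more widely in their tissues was not tested.

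More genes reached an unadjusted p under 0.05 at 7.87 µM than at 25.1 µM at 4 dpf, 2482 against 540. The model gave all groups 1 estimate of the spread. The median SD of log2 CPM was 0.586 at 7.87 µM, but 0.347 at 25.1 µM and 0.338 in DMSO. Fitted on the 12 libraries of each comparison alone the numbers were 1336 and 581, so the size of the excess depended on which libraries were fitted. Digestive content is argued against, since with its scores as terms the number at 7.87 µM was 2673. With the column block as a term it was 1034, the median size of the log2 fold change moved from 0.211 to 0.157 and its SE from 0.25 to 0.262, so a pool difference may account for part of the excess, as all 6 libraries of 7.87 µM lay in the first 32 columns. Surrogate variables, an alternative fixed in advance, gave 1132 genes, a median size of 0.116 and an SE of 0.174. Their log2 fold changes had a correlation of 0.465 with the main ones over 14335 genes. What these variables stand for was not tested. A single library remains open: without H of 7.87 µM the number was 1651, the lowest of 12 (highest 3688, without B), while the 540 ran from 410 to 859, the latter without H of 25.1 µM.

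The level of six7 at 5 dpf was 0.72 ± 0.16 log2 units higher at 25.1 µM, with an edgeR adjusted p of 0.617. It was 0.67 ± 0.16 with the column block as a term and 0.65 ± 0.16 with the digestive scores, so neither accounts for all of it. More photoreceptor RNA would raise the phototransduction list alike, but its median was 0.09 (median absolute deviation 0.19) over 58 members, of which 1, guca1e at 0.90, lay above six7. A response of six7 to PFHxS may be put as a hypothesis only, found and tested on the same data, since the gene did not pass in the full set of genes and chance was not excluded for that comparison.

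For each comparison 40 splits of the compared libraries, the real one included, were refitted on those libraries alone. Between ages chance can be excluded: 1 of 40 splits, the real one, gave as many genes past the threshold, 10474 against 0 for the highest other. It cannot be excluded for the others, counted at an unadjusted p under 0.05. At 4 dpf 21 splits gave as many genes as 25.1 µM (real 581, highest other 3708), 20 as 14 µM (469 and 4029) and 6 as 7.87 µM (1336 and 3415). At 5 dpf 16 did for 25.1 µM (756 and 4627), 32 for 14 µM (488 and 4299) and 5 for 7.87 µM (1478 and 2976). For the difference between ages it was 16 splits (941 and 3618), for the slope at 4 dpf 37 (231 and 3494) and for that at 5 dpf 29 (428 and 3119). For lists called by camera at 25.1 µM, 3 splits gave as many at 4 dpf (20 and 25) and 20 at 5 dpf (13 and 22). Splits that call several times as many genes as the real one point to a structure among the pooled samples that the groups do not follow.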

How the results depend on the processing

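The column block, digestive scores, robust dispersion, DESeq2 filtering at 0.05 or unfiltered, the exact list test, filtering on the 4 groups of an age and the left-out sets were chosen only after the result was seen. At 25.1 µM and 4 dpf the 0 of edgeR (540 at an unadjusted p under 0.05; DESeq2 and limma 0) became 1 on the compared groups alone, where fewer libraries and genes entered the fit. At 14 µM DESeq2 gave 1 in each of its 3 settings and limma 1. At 7.87 µM DESeq2 gave 10, 27 with filtering at 0.05 and 8 unfiltered. At 25.1 µM and 5 dpf DESeq2 gave 1 in each of its 3 settings, surrogate variables 3, the 24 libraries of that age 1 and the compared groups 2; at 14 µM surrogate variables gave 2. The slope at 5 dpf called 1 gene, 0 with ranks and 2 with the digestive scores. Between ages the 8682 genes became 1152 with surrogate variables and 3074 with digestive scores, and 4 named genes turned negative with surrogate variables, c6ast4 (-0.87), ela2l (-0.44), chia.1 (-0.053) and cel.2 (-1.34). Of the lists at 25.1 µM, 20 at 4 dpf and 12 at 5 dpf, none was called at either age with an estimated correlation (0), by fry (0) or by the exact test (0). The cause was not tested for these changes.

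Leaving out each library in turn gave 0 to 1 genes at 14 µM and 0 to 128 at 7.87 µM at 4 dpf (128 without DMSO F, 2 without 7.87 µM A), 7466 to 8726 between ages, and 0 to 0 at 25.1 µM at both ages, at 14 and 7.87 µM at 5 dpf and for the interaction. At 7.87 µM and 5 dpf the 972 genes at an unadjusted p under 0.05 became 185 without the 3 libraries with under 15% of counts in 10 genes. Same-letter libraries tended to deviate together, but not in every pair: the mean correlation was 0.284 over 23 pairs at 4 dpf (19 over 0.1, lowest -0.105) and 0.173 over 28 at 5 dpf (17 over 0.1, lowest -0.247), against -0.0336 and -0.0254 for different letters. Of 24 and 23 libraries, 9 and 9 correlated best with their own letter. The letter may mark a source shared by pools, which the labels do not name and the main model leaves out. If so, the main p-values treat related pools as independent. With the replicate block the slope at 5 dpf called 0 genes and camera 13 lists at 25.1 µM and 4 dpf; the block could not be fitted between ages. Of 436 values of named genes under alternatives 406 were counted as the same. They kept their side of the threshold, with the same direction if called and within 1 SE of the main value if not. A change of sign was counted as reversed only where a fit called the gene. Of the rest 14 moved, 7 weakened, 5 strengthened and 4 reversed. With 6 pools a group, simulated changes of 1.5-fold were recovered in 10% of genes at 4 dpf and 12% at 5 dpf. These rates hold for many genes changed together and would be lower if only a few had changed. Most changes of that size may therefore have been missed.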

Other observations

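The values here were picked out only after the result was seen. Expression of tat, a liver enzyme that glucocorticoids induce, was 26.4 ± 8.76 CPM (SD, n = 6) in DMSO at 5 dpf, 14.9 ± 6.12 at 7.87 µM, 16.2 ± 6.50 at 14 µM and 13.1 ± 4.09 at 25.1 µM, while fkbp5, another glucocorticoid target, had 97.6 ± 27.3 CPM in DMSO and 151 ± 19.1 at 25.1 µM. The log2 fold change of tat at 25.1 µM was -1.02 ± 0.39 (SE; edgeR p 0.0123, adjusted p 1). The liver list mean also lay below DMSO at 5 dpf, by 0.856 at 7.87 µM, 0.345 at 14 µM and 0.303 at 25.1 µM. At 14 µM libraries A and D stood apart, with means of 3.71 and 3.77 (others 5.06 to 5.7), and the DMSO group of 5 dpf held neither letter. The difference from DMSO there was -0.123 without A and -0.135 without D. At 25.1 µM it was -0.15 without D and -0.192 without C.

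Library F of 7.87 µM at 5 dpf held 0.198% of its counts in zgc:158463 and 0.246% in CT027638.1, where the means over all libraries were 5.79% and 5.82%. Library I of the same group held 1.61% and 2.32%, and library H of 7.87 µM at 4 dpf 1.77% and 2.28%.

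Effects of different concentrations share their DMSO libraries, so their correlation across genes, which are not independent replicates, lies above 0 without any effect. Simulated unchanged groups of equal spread gave 0.502. At 4 dpf the observed values were 0.595 for 7.87 and 14 µM, 0.392 for 7.87 and 25.1 µM and 0.543 for 14 and 25.1 µM, and with the DMSO libraries split between the effects they averaged 0.242, 0.093 and 0.115 over 20 splits. These ran from -0.0699 to 0.457, from -0.173 to 0.281 and from -0.11 to 0.244, so each range spanned 0. The covariances were 0.0644, 0.0429 and 0.044 against a simulated 0.0463, and averaged 0.0321, 0.0107 and 0.0118 with the DMSO libraries split. The simulation gave all groups the same SD per gene, pooled over the 8 groups. DMSO varied least at each age (median SD 0.338 at 4 dpf and 0.264 at 5 dpf), so both simulated values are too high a mark. They do not show whether the observed values exceed those without any effect. At 5 dpf the correlations were 0.479, 0.431 and 0.603, with split controls 0.215 (0.00753 to 0.438), 0.16 (-0.108 to 0.336) and 0.192 (-0.105 to 0.435) on average, and the covariances 0.0363, 0.0298 and 0.0285.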
